A study of Mus musculus with 6 samples.

How the data were processed

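Primary visual cortex (V1) of 3 wild-type mice was micro-dissected at postnatal day 28 after 3 days of closure of the right eye, per the labels' protocols. RNA was extracted with TRIzol, and 6 libraries were made with a stranded total RNA kit (SMARTer Stranded, v2). Left V1 was contralateral and right V1 ipsilateral to the closed eye, and the labels give both libraries of a number the same mouse. Total RNA keeps circular RNAs, which lack a poly(A) tail, and also keeps unspliced RNA and any ribosomal RNA that depletion leaves behind.

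The deposited gene table held raw read counts per Ensembl gene, 1 column per library, in the layout of a featureCounts table per the file headers. The deposited circRNA table held raw counts of back-splice reads per circRNA with coordinates, strand and host gene, per the file headers. The submitters' processing notes name HISAT2, featureCounts, DESeq2, limma and the build GRCm38, with no versions or roles. The circRNA caller, its filters, the strand setting of the gene counts and the annotation release are not given in the sources used here. Without the strand setting, counts of a gene that overlaps a gene on the other strand are uncertain. Each of the 1488 circRNAs had at least 1 read in each library, so circRNAs seen in fewer libraries were not analysed here. The authors also deposited normalized circRNA signal values, 1 file per library with gene names and no coordinates. All 1488 equal the raw counts after quantile normalization, compared to 4 decimals, and they were used only as an alternative.

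The gene table held 52636 genes, of which 17848 had no read in any library. Gene symbols and positions came from GENCODE M21 (GRCm38), in which 52489 of the IDs were found, and 95.2% of those genes had the same bounds as in the deposited table. IDs without a match held 0.0473% to 0.0551% of a library's reads. Columns of samples of other series numbered 0. Libraries held 17849253 to 32213500 gene reads and 13428 to 26867 back-splice reads. A circRNA had a median of 6 reads per library, and 148 had a mean of at least 20, so for most circRNAs small changes were not detectable at this depth. Reads carried no molecular identifiers used here, so intervals cover counting error only. No pair of libraries was a duplicate: correlations of log2 CPM lay between 0.976 and 0.988, and at most 0.716% of genes had identical counts.

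Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for figures. The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes were compared between contralateral and ipsilateral V1 with edgeR's quasi-likelihood test (TMM scaling, filterByExpr with a minimum count of 10 and total of 15, 20473 genes), with Benjamini-Hochberg adjustment and a threshold of 0.05. CircRNAs were compared in the same way (TMM on back-splice counts, at least 2 reads in 3 libraries, 1468 circRNAs). Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. Levels are CPM with TMM scaling, as mean ± SD over 3 libraries, and all fold changes are contralateral against ipsilateral. The ratio of circular to host counts was tested with limma (empirical Bayes with a trend) on log2((circRNA count + 0.5) / (host count + 0.5)) for 1428 circRNAs with a host among the tested genes. CircHomer1 and Cdr1as were identified by coordinates and strand. Single values were compared with exact two-sided permutation tests of 3 against 3 libraries, which cannot give a p below 0.1, or exact sign-flip tests over 3 mice, which cannot go below 0.25.

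Of 31 gene lists, 30 had at least 5 tested members and were tested with limma's camera (preset correlation 0.01, and a correlation estimated from the data) and fry, adjusted over the lists. Of the 12 calls at the preset correlation, that of the immediate early genes alone held with an estimated correlation. Named genes were 12 fixed genes and circHomer1, then up to 12 genes per direction with the largest change among those that passed, had a mean CPM of at least 1 and moved the same way in 3 mice. Where fewer than 10 passed, as for circRNAs, the 8 with the smallest p per direction were named, and each list that passed or held a passing gene gave up to 4 members with the smallest p. Predicted genes were counted but not named, and the single values of a few genes that the rule selects are not reported here. Dusp6, Egr3, Inhba, Scg2 and the abundant circRNAs after Cdr1as were named after their values were seen.

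Because both hemispheres come from the same animals, the libraries are paired. Deviations from the group means correlated within mice at 0.706, 0.261 and 0.427 for mice 1 to 3, above the highest value with another mouse (-0.376, 0.0616 and 0.363). The comparison without the mouse as a block was chosen first, and a fit with the block was set beside it. A split of the libraries by mt-Rnr1 at 1000 CPM was seen in the data, and fits with this level as a term, within the low and high libraries, and with the block but without mouse 3 were chosen after seeing the data. The other settings tried were DESeq2 size factors, upper-quartile scaling, DESeq2 with and without the block, limma-voom, no filter, a mean count of at least 50, an adjusted p under 0.1, the block with a correction for gene length, at least 5 reads per circRNA, library sizes from gene counts, the normalized circRNA values (log2 with a pseudocount of 1), a ratio pseudocount of 1, and leaving out each library and each mouse.

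The tests were tried on simulated counts with 200 changed features. Without the block, 0.5%, 71.5% and 99.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and with the block 23%, 77% and 100%. For circRNAs the shares were 0.5%, 0.5% and 58.5% without and 0.5%, 1% and 53.5% with the block, and the ratio test recovered 16% at 4-fold. The simulated counts had the same dispersion for all features of a kind and no difference by mt-Rnr1 level. For the ratio test, hosts were drawn at random from the tested genes. Recovery in the real data may therefore differ from these shares. In a simulated list comparison camera called the shifted list and 0 of 9 others. Mice without deprivation were not analysed here, so hemisphere and deprivation are not separated in these samples.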

Results

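RNA was measured in the primary visual cortex (V1) of wild-type C57BL/6J mice at postnatal day 28, after the lids of the right eye had been sutured for 3 days. This monocular deprivation falls in the juvenile period in which closing an eye alters the cortical responses to both eyes. Left V1, contralateral to the sutured eye, and right V1, ipsilateral to it, were dissected from the same 3 mice, which gave 3 contralateral and 3 ipsilateral libraries of total RNA. Each library was counted both over genes and over circular RNAs (circRNAs), closed RNA loops recognised by reads that cross a back-splice junction. The study asks how deprivation relates to circHomer1, a circRNA made from exons of the synaptic scaffold gene Homer1. Reads assigned to genes numbered 20172439, 17849253 and 21818822 in contralateral libraries 1 to 3 and 20749614, 32213500 and 23564051 in the ipsilateral ones. Back-splice reads were far rarer, with 13428, 17312 and 19326 in the contralateral and 14019, 26867 and 18173 in the ipsilateral libraries. The libraries also fell into a low and a high set by mt-Rnr1, the mitochondrial 12S ribosomal RNA. It stood at 28.7, 34.6 and 15.02 CPM (read counts scaled to library size) in contralateral 1, ipsilateral 1 and ipsilateral 3, against 2346, 5759 and 4823 CPM in contralateral 2, contralateral 3 and ipsilateral 2. Because this split does not follow the hemispheres, values within each set are given beside the main comparisons over all libraries. In each set one hemisphere has a single library, assumed to vary like the others.

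The first comparison asked which genes differed between the hemispheres. Genes switched on by neuronal activity were lower in the V1 opposite the deprived eye. Egr2, an activity-induced zinc finger transcription factor, stood at 3.48 ± 1.55 CPM (SD, n = 3) in contralateral and 26.99 ± 5.31 CPM in ipsilateral V1, 7.74-fold lower. Fos, a subunit of the AP-1 transcription factor, was 4.05-fold lower (10.1 ± 3.54 against 41.1 ± 4.97 CPM), and Nr4a1, an orphan nuclear receptor, was 3.28-fold lower (38.5 ± 6.63 against 126 ± 14.7 CPM). Arc, which regulates AMPA receptor endocytosis at synapses, went from 281 ± 17.4 CPM in ipsilateral to 107 ± 37.9 CPM in contralateral V1. Bdnf, the neurotrophin of activity-dependent plasticity, went from 57.0 ± 13.5 to 19.8 ± 1.82 CPM.

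In edgeR's quasi-likelihood test, 26 of 20473 genes passed an adjusted p under 0.05, and all 26 were lower in contralateral V1 in each of the 3 mice. The median log2 fold change of these 26 genes was -1.35, against 0.03 over all genes tested. The log2 fold changes were -2.95 (SE 0.29, adjusted p = 0.00165) for Egr2 (chromosome 10, 67535475 to 67542188), -2.02 (SE 0.21, adjusted p = 0.00263) for Fos (chromosome 12, 85473890 to 85477273) and -1.71 (SE 0.15, adjusted p = 0.00125) for Nr4a1 (chromosome 15, 101254269 to 101274795). Other large falls were Fosb (-1.72), Nptx2 (-1.67), Ptgs2 (-1.58), Egr1 (-1.56), Fosl2 (-1.55), Cdkn1a (-1.54), Bdnf (-1.52), Arc (-1.39) and Nr4a3 (-1.38), with adjusted p from 0.00373 for Bdnf to 0.0335 for Arc. Nptx2 encodes a secreted pentraxin that clusters AMPA receptors, Ptgs2 the inducible cyclooxygenase, and Cdkn1a an inhibitor of cyclin-dependent kinases. Homer1 (ENSMUSG00000007617, chromosome 13, 93299635 to 93405129, plus strand), whose products link glutamate receptors to the postsynaptic scaffold, fell by 1.01 on the log2 scale (SE 0.17, adjusted p = 0.0416), from 828 ± 117 CPM in ipsilateral to 411 ± 74.8 CPM in contralateral V1. Among the genes fixed for naming beforehand, Npas4 (-1.26, adjusted p = 0.587), Igf1 (-0.60, 0.563), Gad1 (-0.56, 0.278), Pvalb (-0.38, 0.786) and Mbp (-0.08, 0.962) did not pass.

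Fitting the mouse as a block raised the count to 183 genes, 143 lower and 40 higher, and included all 26. Npas4 (adjusted p = 1.71e-04), Gad1 (0.00558) and Igf1 (0.0494) then passed as lower, while Pvalb (0.218) and Mbp (0.758) did not. Over all alternatives the adjusted p of Npas4 ranged from 5.41e-09 to 1.00, that of Gad1 from 1.71e-05 to 1.00 and that of Igf1 from 0.0183 to 1.00. Within the low mt-Rnr1 libraries 38 genes passed (32 lower, 6 higher) and within the high ones 28 (26 lower, 2 higher), of which 20 and 17 were among the 26. The 26 genes had a median of -1.59 within the low libraries and -1.11 within the high ones, and for Homer1 the 2 values were -1.42 and -0.64. Homer1 no longer passed without contralateral library 1 (adjusted p = 0.0533) or 2 (0.343), ipsilateral library 1 (0.0548), 2 (0.0618) or 3 (0.116), with a range of 3.39e-09 to 0.742 over all alternatives. Without contralateral library 2, or without both libraries of mouse 2, 0 genes passed in edgeR, with 799 and 503 genes at an unadjusted p under 0.05 against 1259 in all libraries, while the median of the 26 genes stayed at -1.33 and -1.40. The count was 16 without ipsilateral library 2 and without mouse 3, and 51 without mouse 1, and all 26 genes kept a negative sign in each of these fits.

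**Figure D1:**
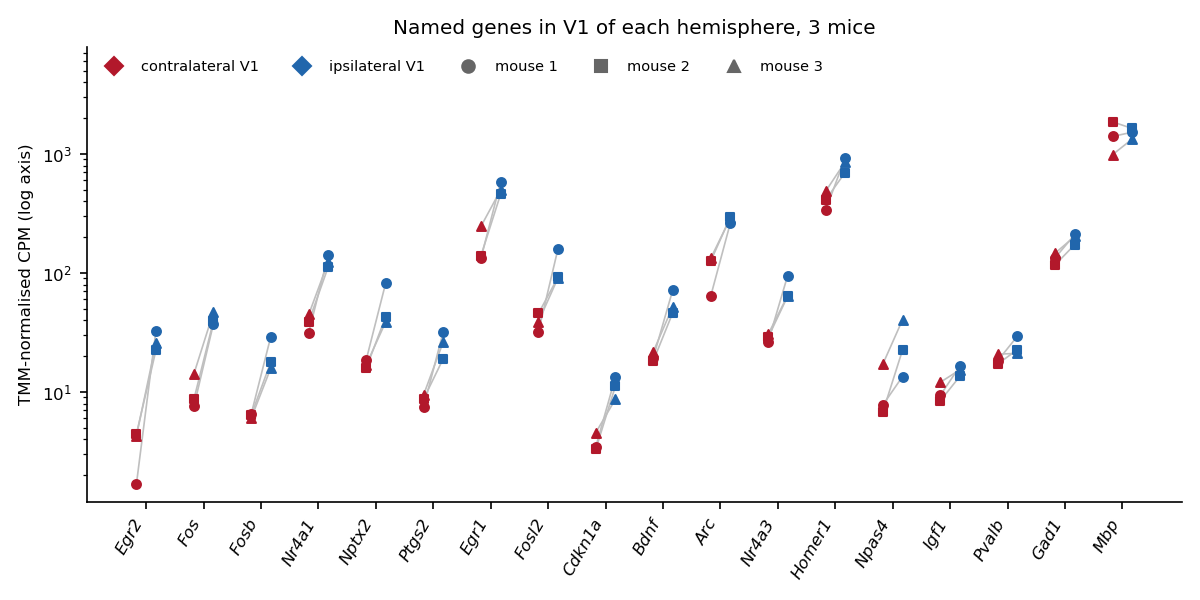
Normalised expression (CPM, log axis) of named genes in contralateral (red) and ipsilateral (blue) V1, with 1 point per library, marker shapes for the 3 mice and grey lines joining the hemispheres of a mouse. From Egr2 to Homer1 each mouse had the lower value in contralateral V1, as for Egr2 with means of 3.48 and 26.99 CPM, whereas Mbp lay lower there in 2 of 3 mice.

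Lists of genes chosen for the tissue and the treatment placed these genes in groups. Of 23 immediate early genes tested, the rapid transcriptional response of neurons to activity, 13 fell in contralateral V1 over all genes tested and 19 when adjusted over the list alone. None rose, and the list median was -1.26 (log2). Junb (-1.27, adjusted p = 0.00165), the phosphatase gene Dusp6 (-1.32, 0.00603) and Egr3 (-0.94, 0.0315) were among those that fell. Jun (0.07, 0.953) and Klf2 (0.10, 0.951), named after their values were seen, did not pass and lay on the other side of 0. Of 20 late activity-regulated genes, some of which encode synaptic or secreted proteins, 7 fell over all genes and 18 when adjusted over the list alone. The list median was -0.76. The 7 were Bdnf, Ptgs2, Nptx2, Homer1, the prohormone convertase gene Pcsk1 (-1.14, adjusted p = 0.00903), the activin subunit gene Inhba (-1.04, 0.0340) and the secretogranin gene Scg2 (-0.77, 0.0481).

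Both lists passed camera, a test of a list against all other genes, at its preset correlation of 0.01 (adjusted p = 6.13e-45 and 1.02e-33 over 30 lists). Both also pointed down within the low and within the high mt-Rnr1 libraries, where a hemisphere has a single library. With an estimated correlation the immediate early genes kept their call (adjusted p = 0.0174 with an estimated correlation) and the late genes did not (adjusted p = 0.0775 with an estimated correlation). The fry test, which asks whether a list's genes move one way on balance without comparing them with other genes, gave adjusted p = 0.00604 and 0.0341. With the mouse as a block, neither list passed with an estimated correlation (adjusted p = 0.478 for both) or in fry (0.254 for both), although 19 and 13 of their genes passed singly. None of the 30 lists passed either test in that fit. There 6 libraries leave little from which to estimate the spread, so these 2 losses decide little.

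Of 19 markers of GABAergic interneurons, none passed over all genes, 6 fell when adjusted over the list alone, and 4 fell with the mouse as a block. Those 4 were Vip, the peptide of a class of disinhibitory interneurons (-0.62, adjusted p = 0.200 without and 0.00754 with the block), the GABA-synthesising enzyme genes Gad1 and Gad2 (-0.48, 0.452 and 0.0301), and Dlx6os1 (-0.54, 0.553 and 0.0451). Over all alternatives their adjusted p ranged from 0.00197 to 1.00 for Vip, 0.00242 to 1.00 for Gad2 and 0.0337 to 1.00 for Dlx6os1. Pvalb (-0.38) and, named after its values were seen, Sst (-0.51) did not pass in either fit. The list median was -0.35, and its preset call (adjusted p = 8.08e-09) was lost with an estimated correlation (adjusted p = 0.284 with an estimated correlation). The list pointed down within the low and within the high mt-Rnr1 libraries, where a hemisphere has a single library.

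Synaptic lists lay closer to 0. No gene passed among 18 GABA receptor and inhibitory synapse genes (median -0.18), with Gabra2 (-0.35) and Gabra5 (-0.42) among those at the smallest p, or among 22 presynaptic vesicle release genes (median -0.14), led by Snap25 (-0.36), Sv2a (-0.30), Nrxn3 (-0.20) and Syt1 (-0.25). In the postsynaptic scaffold and adhesion list 1 of 28 genes fell, Homer1 (median -0.06), ahead of Lrrtm3 (-0.35), Lrrtm2 (-0.28) and Cacng3 (-0.22), which did not pass. In the IGF1 and BDNF signalling list 1 of 22 genes fell, Bdnf (median -0.03), and with the mouse as a block 3 did: Bdnf, Igf1 and the insulin receptor substrate gene Irs2 (-0.54, adjusted p = 0.744 without and 0.0305 with the block), with Ntrk3 (-0.25) not passing. Of 26 genes for circRNA biogenesis and neuronal RNA-binding proteins none passed without the block (median -0.06), and 1 fell with it, Elavl2 (-0.50, adjusted p = 0.504 and 0.0171), ahead of Nova1 (-0.33), Elavl4 (-0.31) and Elavl1 (-0.20). Over all alternatives the adjusted p ranged from 6.70e-04 to 1.00 for Irs2 and from 0.00318 to 1.00 for Elavl2. The counts adjusted over the list alone were 0, 0, 1, 1 and 0 for these 5 lists. Their preset calls (adjusted p = 1.84e-05, 6.33e-04, 0.0228, 0.0159 and 0.0468, in the order given) were lost with an estimated correlation (adjusted p = 0.540, 0.655, 0.655, 0.655 and 0.655 with an estimated correlation). Within the low mt-Rnr1 libraries the GABA receptor list alone of these 5 passed at the preset correlation (0.0463, then 0.496, 0.861, 0.267 and 0.276), and within the high ones all but the last (7.65e-04, 0.00349, 0.0410, 0.00895 and 0.0972).

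The 4 remaining called lists, of cell markers and RNA quality, passed at the preset correlation without any gene passing over all genes. Layer 6 neuron markers had a median of -0.22, and with the mouse as a block Tle4 (-0.41, adjusted p = 0.525 without and 0.0393 with it) and the matricellular protein gene Ccn2 (-0.83, 0.550 and 0.00849) fell, the 2 that also fell when adjusted over the list alone, while Cplx3 (-0.29) and Oprk1 (-0.73) did not pass. Over all alternatives the adjusted p ranged from 0.0151 to 1.00 for Tle4 and from 0.00229 to 1.00 for Ccn2. Oligodendrocyte and myelin markers had a median of -0.23, with Cldn11 (-0.34), Ugt8a (-0.37), Mog (-0.33) and Ermn (-0.32) at the smallest p. Microglial markers had a median of 0.18, with Siglech (0.26), Trem2 (0.36) and Cx3cr1 (0.21) among those at the smallest p. Mitochondrially encoded genes had a median of 0.43, with mt-Co2 (0.63), mt-Cytb (0.51), mt-Nd4 (0.44) and mt-Atp6 (0.41), and followed the mt-Rnr1 level: medians were -0.16 and 0.20 in mice 1 and 2 and 1.22 in mouse 3, whose hemispheres lie in different mt-Rnr1 sets. Within the low set mt-Cytb (-0.10), mt-Nd4 (-0.08) and mt-Atp6 (-0.01) changed sign. The mitochondrial share of gene reads was 4.46 ± 1.94% contralateral and 3.26 ± 1.65% ipsilateral (exact two-sided permutation p = 0.3, n = 3). None of the oligodendrocyte, microglial or mitochondrial genes passed adjusted over the list alone. The preset calls of the 4 lists (adjusted p = 0.0165, 2.22e-05, 0.0159 and 0.0165) were lost with an estimated correlation (adjusted p = 0.540, 0.655, 0.655 and 0.655 with an estimated correlation). At the preset correlation, layer 6 and oligodendrocyte markers passed within the high (6.13e-04 and 1.64e-09) but not the low mt-Rnr1 libraries (0.464 and 0.267), microglial markers within the low (0.0463) but not the high ones (0.175), and mitochondrial genes in neither (0.920 and 0.692).

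The other 18 tested lists did not pass camera over all libraries at the preset correlation. Medians of neuronal lists were -0.06 for glutamate receptors (adjusted p = 0.0882), -0.04 for layer 2-3 (0.887), 0.05 for layer 4 (0.887) and -0.11 for layer 5 neurons (0.112). Those of other cells were 0.04 for astrocytes (0.848), -0.02 for oligodendrocyte precursors (0.887), 0.08 for endothelial and mural cells (0.887), -0.13 for meninges and fibroblasts (0.0882) and 0.07 for blood (0.502). Neighbouring regions gave -0.22 for hippocampus (0.150), 0.02 for thalamus (0.906), 0.03 for striatum (0.910) and 0.11 for retrosplenial cortex (0.910). The remaining pathways gave -0.01 for the perineuronal net and matrix (0.572), 0.13 for complement and pruning (0.910), 0.02 for heat shock and stress (0.150), -0.01 for the circadian clock (0.887) and 0.03 for cytosolic ribosomal proteins (0.660). The heat shock list held 1 gene that fell, Cdkn1a, ahead of Hspa8 (-0.40), Hsph1 (-0.34) and Hsp90aa1 (-0.34), which did not pass. Its mean (-0.08) and test pointed down against a median above 0. Mean and median also differed in sign for layer 2-3 neurons (mean 0.05), oligodendrocyte precursors (0.02), the perineuronal net list (0.01), the circadian clock (0.00) and retrosplenial cortex (-0.04), where the test followed the median. Adjusted over the list alone, 2 layer 2-3 genes rose and 2 fell, 1 layer 5 gene, 1 heat shock gene and 1 retrosplenial gene fell, and no gene passed in the other 14 lists. With the mouse as a block, over all genes, 2 layer 2-3 genes rose and 2 fell, and 1 gene fell in each of the layer 5 (Etv1, -0.51), retrosplenial (Nr4a2, -1.13) and complement (C1ql3, -0.53) lists, the last 3 named after their values were seen. Within the low mt-Rnr1 libraries none of the 18 lists passed (adjusted p from 0.0725 to 0.989). Within the high ones 6 passed as lower: meninges and fibroblasts (7.65e-04), heat shock (0.0165), hippocampus (0.0285), layer 5 (0.0395), oligodendrocyte precursors (0.0409) and the perineuronal net list (0.0410). With the mt-Rnr1 level as a term, meninges and fibroblasts (7.15e-04) and layer 5 (0.0376) passed as lower. Calls also moved with single libraries: meninges and fibroblasts passed as lower without contralateral library 2 (0.00288) or ipsilateral library 3 (6.73e-05), heat shock (0.0290) and layer 5 (0.00574) without contralateral library 3, and ribosomal proteins, as higher, without ipsilateral library 1 (0.0230). Without mouse 3, meninges and fibroblasts (0.00134), layer 5 (0.00634), heat shock (0.00813) and glutamate receptors (0.0444) passed as lower. Choroid plexus, with 2 genes tested (0.14 and -0.10), was too small for the test.

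**Figure D2:**
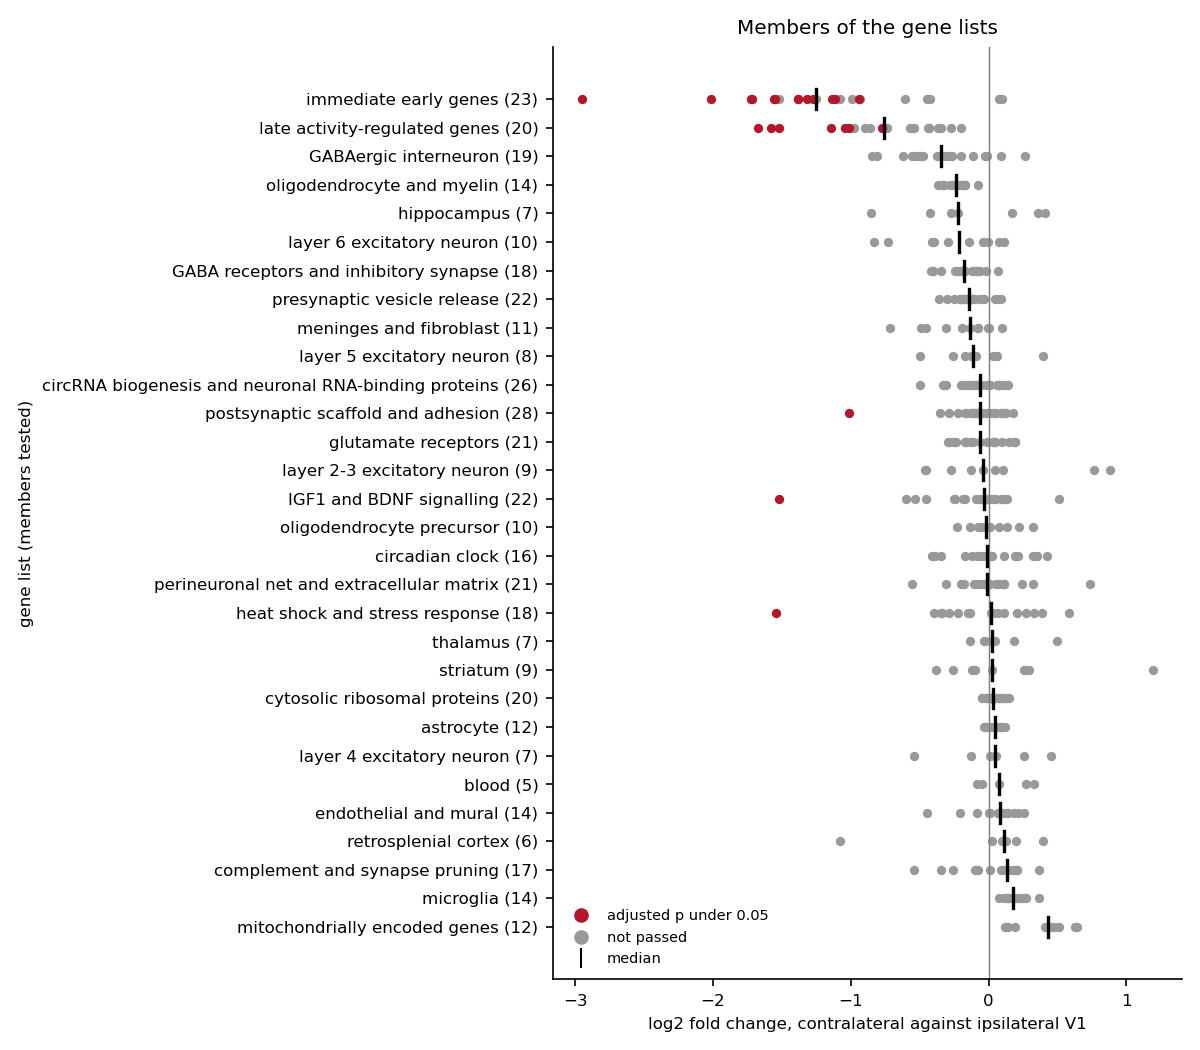
Log2 fold change (contralateral against ipsilateral V1) of each tested member of 30 gene lists, 1 row per list with its number of tested members. Red points passed an adjusted p under 0.05 over all genes, grey points did not, and black bars are medians, which are lowest for immediate early genes (-1.26) and late activity-regulated genes (-0.76).

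The second comparison asked whether circRNAs differed between the hemispheres. The table held 1488 circRNAs, of which 1468 were tested, with 885 host genes on the same strand among those tested. Of the 1488, 1400 joined exons, and the median was 6 reads per circRNA and library. The most abundant was Cdr1as, the circRNA antisense to Cdr1 that carries many sites for miR-7 (chromosome X, 61183248 to 61186174, plus strand), at 14.3% of all back-splice reads. Its level was 141750 ± 2893 CPM of circRNA reads in contralateral and 144890 ± 5625 in ipsilateral V1 (log2 fold change -0.03, SE 0.07, adjusted p = 0.999; exact two-sided permutation p = 0.4, n = 3), and the difference was -0.059 within the low and -0.025 within the high mt-Rnr1 libraries. CircTulp4 (-0.15, SE 0.15), circAtxn1 (-0.37, SE 0.19) and circAnkrd12 (-0.14, SE 0.21) came next in abundance, and none passed (adjusted p = 0.999 for each). In all, circRNA reads came to 840 ± 157 CPM of gene-assigned reads in contralateral and 760.3 ± 79.8 in ipsilateral V1, a difference of 80.1 within the spread between libraries (exact two-sided permutation p = 0.5, n = 3; the smallest p possible is 0.1). The total level followed mt-Rnr1, at 666, 676 and 771 in the low libraries and 970, 886 and 834 in the high ones. The high set holds 2 contralateral libraries and 1 ipsilateral library. The difference between hemispheres was -57.8 within the low mt-Rnr1 libraries and 93.8 within the high ones, so its direction did not hold within both sets. It was 15.4 without contralateral library 2 and 168 without contralateral library 1.

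None of 1468 circRNAs tested passed in edgeR, where 52 had an unadjusted p under 0.05. The count was also 0 with the mouse as a block (66), with the mt-Rnr1 level as a term (66), in DESeq2 (17), in DESeq2 with the block (5) and in limma-voom (55). With few reads per circRNA the test had little reach: in simulated data it recovered 58.5% of 200 circRNAs changed 4-fold but 0.5% of those changed 2-fold. The smallest p in either direction belonged to circCdyl (chromosome 13, 35815909 to 35816575; log2 fold change 1.38, SE 0.41, adjusted p = 0.999, range over alternatives 0.00921 to 1.00) and to circNab1 (chromosome 1, 52479238 to 52490755; -1.13, SE 0.41, adjusted p = 0.999). CircCdyl followed the mt-Rnr1 level, with 7, 5 and 7 reads in the 3 low libraries and 43, 51 and 34 in the high ones. It passed without contralateral library 1 (adjusted p = 0.0325) and without ipsilateral library 2 (0.00921), where circNbea (chromosome 3, 56079859 to 56091120; 2.40, adjusted p = 0.0114), singled out after its values were seen, passed too. CircNbea reads also followed the mt-Rnr1 level, with 10, 3 and 7 in the low libraries and 33, 44 and 60 in the high ones, and the library left out holds its highest count. The other circRNAs with the smallest p, none of which passed, were circDgki (2.16), circMalat1 (1.23), circSrgap1 (2.14), circZfp644 (1.93), circSnap91 (1.81), circMtif2 (1.77) and circCacna2d3 (1.66) on the higher side. On the lower side they were circAtad2b (-2.26), circAnkef1 (-2.19), circSipa1l1 (-1.30 and -1.76 for 2 circRNAs), circZcchc17 (-1.93), circElf2 (-0.77) and circSrbd1 (-1.87). Among the higher ones, circMalat1 too followed the mt-Rnr1 level, with 9, 9 and 9 reads in the low libraries and 37, 33 and 20 in the high ones. When circRNAs were grouped by the lists of their host genes, none of 7 lists passed camera, and the smallest adjusted p was that of the circadian clock (0.324, 6 circRNAs, median -0.45).

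**Figure D3:**
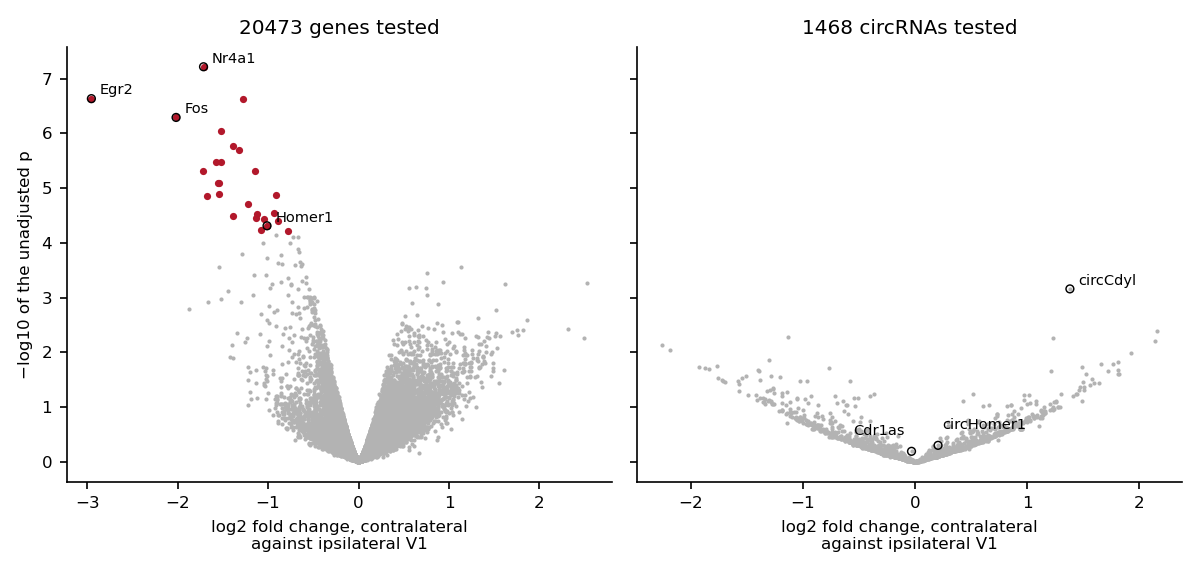
Unadjusted p (as -log10) against log2 fold change (contralateral against ipsilateral V1) for 20473 genes and 1468 circRNAs, 1 point each. The 26 genes in red passed an adjusted p under 0.05 and all lie on the lower side, and no circRNA passed.

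The third comparison concerned circHomer1. CircHomer1 did not differ detectably between the hemispheres, while reads of its host gene were lower in contralateral V1. It was the most abundant of 3 Homer1 circRNAs and spans chromosome 13, 93341756 to 93356079 on the plus strand (GRCm38), from the start of exon 2 to the end of exon 5 of the protein-coding transcript Homer1-203, 522 bases once spliced. Its reads numbered 30, 55 and 61 in contralateral and 25, 74 and 49 in ipsilateral libraries 1 to 3. This was 2835 ± 563 CPM of circRNA reads in contralateral and 2448 ± 587 in ipsilateral V1 (exact two-sided permutation p = 0.5, n = 3). The edgeR log2 fold change was 0.21 (SE 0.30, unadjusted p = 0.498, adjusted p = 0.999), and 0.28, 0.15 and 0.20 in mice 1 to 3, higher in 3 of 3. With the mt-Rnr1 level as a term it was 0.06, and the difference of mean log2 levels was -0.0099 within the low and 0.15 within the high mt-Rnr1 libraries, so the direction did not hold within both sets. The other Homer1 circRNAs, from exons 2 to 4 (93341756 to 93349297; log2 fold change -0.15, SE 0.60) and exons 6 to 9 (93386345 to 93393108; -0.28, SE 0.73), also did not pass.

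Reads of circHomer1 relative to its host were higher in contralateral V1 in 3 of 3 mice, as were those of the other Homer1 circRNAs, with none passing adjustment over all ratios. CircHomer1 gave 5.80 ± 1.36 reads per 1000 Homer1 gene reads in contralateral and 2.37 ± 1.04 in ipsilateral V1 (exact two-sided permutation p = 0.1, n = 3, the smallest p this design allows). The log2 change of this ratio was 1.72, 1.06 and 1.30 in mice 1 to 3 (exact sign-flip p = 0.25, the smallest p that 3 mice allow). Pooled over libraries, 146 circHomer1 reads stood against 24934 Homer1 reads in contralateral and 148 against 61050 in ipsilateral V1, a ratio of ratios of 2.42 (exact 95% interval 1.91 to 3.06, counting error only). In the limma test of all circular to host ratios the log2 change was 1.36 (SE 0.56, unadjusted p = 0.0252, adjusted p = 0.992), so it did not pass over the 1428 circRNAs with a tested host gene. It was 1.33 within the low and 0.91 within the high mt-Rnr1 libraries. For the other Homer1 circRNAs the log2 change of the ratio was 1.10 (SE 0.62, exons 2 to 4) and 0.88 (SE 0.65, exons 6 to 9), each with an adjusted p of 0.992 in limma. None of the 1428 ratios passed in limma, where 56 had an unadjusted p under 0.05 (62 with the mouse as a block and 59 with the mt-Rnr1 level as a term, 0 passing in each), and the median log2 change over all ratios was 0.15. Homer1 gene counts pool the long isoforms with the short activity-induced one and include exonic reads from the circRNA itself.

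**Figure D4:**
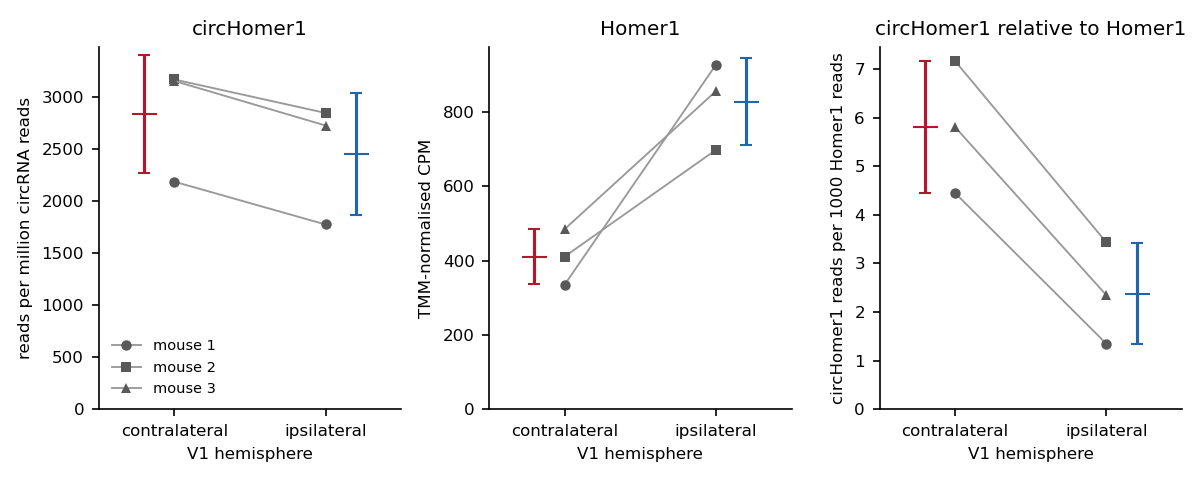
CircHomer1 (CPM of circRNA reads), Homer1 (CPM of gene reads) and circHomer1 reads per 1000 Homer1 reads in each hemisphere of the 3 mice, with lines joining the hemispheres of a mouse and coloured bars for mean ± SD (n = 3). CircHomer1 overlaps between the hemispheres (2835 ± 563 against 2448 ± 587), while Homer1 is lower and the ratio higher in contralateral V1 in all 3 mice.

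**Figure D5:**
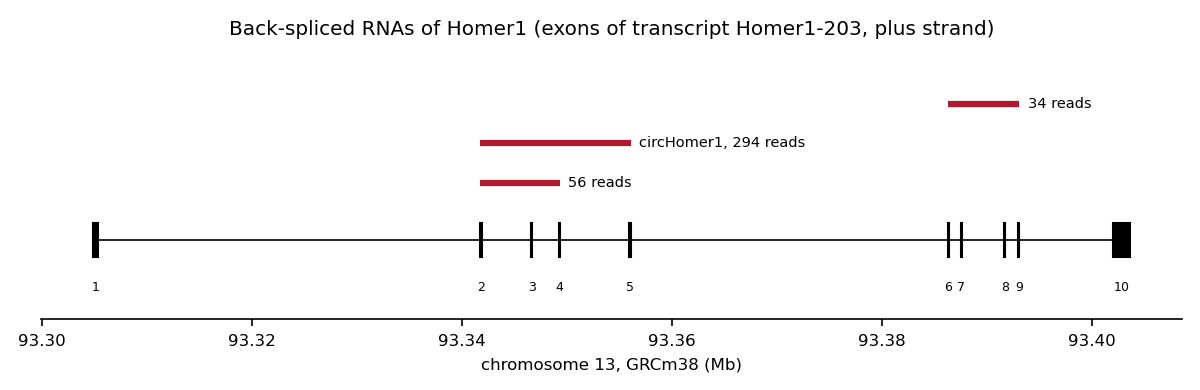
Map of Homer1 on chromosome 13 (GRCm38, position in megabases) with the 10 exons of transcript Homer1-203 in black and the span of each of the 3 circRNAs in red, labelled with reads summed over 6 libraries. CircHomer1 covers exons 2 to 5.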

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

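The fits with the mt-Rnr1 level as a term, within the low or high mt-Rnr1 libraries, and with the block but without mouse 3 were chosen only after the data were seen. All 26 genes called lower kept their sign in every setting, and the number of genes called ranged from 0 to 262. It was 183 with the mouse as a replicate block, 82 in DESeq2, 214 in DESeq2 with the block, 109 with no filter (82.6% of them lower), 102 with the block and a gene length correction, and 262 with the block without mouse 3. It stayed between 19 and 35 with DESeq2 size factors (27), upper-quartile scaling (25), limma-voom (26), a mean count of at least 50 (19), the mt-Rnr1 term (34) and an adjusted p under 0.1 (35). Leaving out single libraries or mice gave 0 (without contralateral library 2 or mouse 2) to 51 genes (without mouse 1). For the genes named by the rule and for the gene lists, the block changed no call beyond those given beside the results. In all, 157 genes were called only with the block, 117 lower and 40 higher, and most of them are not named here. The cause of these differences was not tested, except that leave-outs have fewer samples.

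CircRNAs called numbered 0 in the alternatives run on all libraries and 0 to 2 in the leave-outs, with 2 without ipsilateral library 2. Ratios called numbered 0 in each alternative, and the circHomer1 log2 fold change lay between 0.06 and 0.39 in the fitted alternatives, with a difference of -0.0099 within the low mt-Rnr1 libraries. Gene lists called fell from 12 to 1 with an estimated correlation and to 5 within the low mt-Rnr1 libraries, against 15 within the high ones, and over the leave-outs ranged from 5 without mouse 2 to 14 without mouse 3. The difference in total circRNA level (CPM of gene-assigned reads) reversed to -57.8 within the low mt-Rnr1 libraries, and lay between 15.4 and 168 in the leave-outs.

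Genes and circRNAs that reversed had not passed in the first place. Mbp went to 0.032 with the block without mouse 3, and from -0.33 to 0.12 over the leave-outs, the highest without contralateral library 3. Oprk1 ranged from -1.36 to 0.27 over the leave-outs, the latter without ipsilateral library 2. Within the low mt-Rnr1 libraries mt-Cytb (-0.10), mt-Nd4 (-0.078) and mt-Atp6 (-0.0097) reversed. Cdr1as went to 0.012 with no filter, 0.018 with at least 5 reads and 0.10 with library sizes from gene counts, and ranged from -0.044 to 0.018 over the leave-outs. Over the leave-outs, the Homer1 circRNA of exons 2 to 4 ranged from -0.28 to 0.23 and that of exons 6 to 9 from -0.44 to 0.011. The cause was not tested. Named genes and circRNAs kept direction and call in 78 of 78 cases with each of DESeq2 size factors, upper-quartile scaling, limma-voom and the mt-Rnr1 term. At this depth a 2-fold change of a circRNA was recovered in 0.5% of simulated cases. For circRNAs with few reads the absence of calls therefore sets no limit on changes of that size. For the abundant Cdr1as (log2 fold change -0.03, SE 0.07) the error was small beside a 2-fold change. For circHomer1 (0.21, SE 0.30) it was larger. The values were 0.35 (SE 0.35) with library sizes from gene counts and 0.22 (SE 0.40) in DESeq2, where a rise near 2-fold was not excluded.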

Other observations

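Tests chosen only after the result was seen were the splits of the libraries for genes, circRNAs and gene lists, the mt-Rnr1 term, the neuronal lists and the question of hemisphere, and the genes named here were chosen after their values were seen. With the mouse as a block, 9 genes of cholesterol synthesis and its regulation fell in contralateral V1, though none passed in edgeR with the hemisphere alone in the model, and Hmgcs1 passed with the mt-Rnr1 level as a term (adjusted p = 0.0454). They included Hmgcs1 (log2 fold change -0.64, SE 0.10, adjusted p = 0.00259 with and 0.124 without the block), Idi1 (-0.68, 0.0118 and 0.227) and the sterol sensor Insig1 (-0.54, 0.00849 and 0.296). Each of the 9 was lower in 3 of 3 mice, and their median was -0.49 within the low and -0.64 within the high mt-Rnr1 libraries. Because the 9 were picked for falling in this paired fit, that agreement adds no separate support. Feedback genes of the ERK kinase pathway formed another group: the phosphatase genes Dusp4, Dusp5 and Dusp6 fell without the block, and Spry2 (-0.53, adjusted p = 0.0146), Etv1 (-0.51, 0.0456) and Etv5 (-0.71, 6.37e-04) fell with it.

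Markers of layer 2-3 neurons went both ways with the block. Otof (0.75, SE 0.10, adjusted p = 4.89e-04 with and 0.161 without the block) and Adamts2 (0.84, SE 0.16, 0.0115 and 0.306) rose in contralateral V1, while Lamp5 (-0.47, SE 0.10, 0.0329 and 0.548) and Stard8 (-0.46, SE 0.10, 0.0393 and 0.511) fell. Each kept its sign in every alternative, with log2 fold changes of 0.57 to 1.05 for Otof, 0.47 to 1.39 for Adamts2, -0.60 to -0.36 for Lamp5 and -0.57 to -0.34 for Stard8. Among the 40 genes that rose with the block were also Robo3, an axon guidance receptor (0.76, adjusted p = 4.34e-04), Rnf207 (1.15, 0.0135), the calcium channel gene Cacna1h (0.56, 0.0178) and the neuronal nitric oxide synthase gene Nos1 (0.45, 0.0456), none of which passed with the hemisphere alone in the model. Robo3 (0.94, adjusted p = 0.0164) and Otof (0.82, 0.0365) were the 2 genes that rose with the mt-Rnr1 level as a term. At the Cdr1as locus, back-splice reads were also listed on the minus strand, the strand of Cdr1 (chromosome X, 61184005 to 61185558), with 114, 29 and 18 reads in contralateral and 94, 57 and 8 in ipsilateral libraries 1 to 3. Their bounds (61183248 to 61186174) were those of Cdr1as and reach beyond Cdr1. Whether these reads come from a separate RNA was not tested.

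The fall of the 26 called genes was weighed against a difference in ribosomal RNA depletion, a lower share of neurons and the hemisphere itself. With the mt-Rnr1 level as a term all 26 still passed with a median of -1.33, and the median was -1.59 within the low and -1.11 within the high libraries. Picking genes that differ between hemispheres in the same libraries favours this outcome, so it decides little. The immediate early list, fixed beforehand, had medians of -1.29 in mouse 1, with both libraries low, and -1.24 in mouse 2, with both high. For that list this argues against the mt-Rnr1 level as the whole cause. Depletion of other ribosomal RNA was not tested. A lower share of neurons would lower presynaptic, glutamate receptor and layer markers alike. The median of these 77 genes was -0.12 (-0.10, -0.27 and 0.04 in mice 1 to 3), against -1.74, -1.23 and -1.07 for the called genes. GABAergic interneuron markers were not among the 77 and had a median of -0.35 (-0.58, -0.34 and -0.19 in mice 1 to 3). A lower share of interneurons was therefore not tested. Deprivation of the contralateral eye and a difference between left and right V1 or in the order of dissection cannot be told apart, since left V1 was contralateral in each mouse and 0 undeprived mice were among the samples.

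The higher ratio of circHomer1 to Homer1 reads was weighed next. Counting noise was argued against by the pooled ratio of ratios, whose lower 95% bound was 1.91, and a rise of all circular RNA by the median over all ratios, 0.15, against 1.36 for circHomer1. That circRNAs keep their level when their host gene falls is a candidate explanation, but apart from Homer1 only 2 circRNAs of 2 hosts with a fall of at least 0.5 had enough reads (median difference to the host 0.81), none of these hosts passed, and the requirement of at least 10 circRNAs was set after this number was seen, so it stays open. In the other direction, 9 circRNAs of 4 hosts with a rise of at least 0.5 had a median change of 0.48, beside 0.64 for their hosts. That host median equals the highest change among the mitochondrially encoded genes, whose level followed mt-Rnr1, and 13 circRNAs in the table were mitochondrial. How many of the 9 were mitochondrial was not examined, so they do not show how circRNAs of nuclear hosts behave. The circHomer1 ratio was higher within the low (1.33) and the high mt-Rnr1 libraries (0.91), and whether the short or the long Homer1 isoforms fell was not tested.

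The cholesterol and ERK groups were tested on members that had not been seen when the lists were drawn up. The members seen had all passed with the block, and none of the others had. That 0 of the others passed was therefore fixed by this choice. Their medians also lack the members with the clearest falls, which favours values nearer to 0. The 15 other cholesterol genes had a median of -0.16 with the block (limma camera p = 2.24e-04 at the preset and 0.112 with an estimated correlation) and 0 of them passed in edgeR. Of the 9 other ERK genes 0 passed in edgeR. Their median was -0.22 with the block (limma camera p = 0.00205 at the preset and 0.184 with an estimated correlation), while without the block the p was 0.0442 with an estimated correlation and 0.0451 in fry. For the cholesterol genes these p were 0.213 and 0.295. The requirement that camera also pass with an estimated correlation was added after these values were seen, because other splits of the libraries also gave many preset calls. With the block, little is left from which to estimate the correlation, so failing that test decides little. A coordinate fall of either pathway may be present, but these values leave it open.

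The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes as the real 26 were called in 2 of the 10 splits, the real one included, and the highest other count, 32, came from the split by mt-Rnr1 level. Between hemispheres the 26 genes had a median of -1.59 within the low and -1.11 within the high libraries of that split, where one hemisphere has a single library. Of the 4 splits that part all 3 pairs, the real one called 183 genes with the block and the other 3 called 0 each. Each of those 3 exchanges the hemispheres of a single mouse, so a difference between hemispheres adds to its error and lowers its count. These 4 are also too few for a share under 0.05, so the contrast decides little. For circRNAs (0 called, highest other 24) and ratios (0, highest other 3), each of the 10 splits gives as many by construction, so this decides nothing for them. Both highest values again came from the mt-Rnr1 split, which points to a structure of the libraries. For gene lists 3 of 10 splits gave at least the 12 calls of the real one, with 16 as the highest.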
